A study of Caenorhabditis elegans with 97 samples.

How the data were processed

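Gonad arms of young adult hermaphrodites were frozen, cut into sections of 50 micrometres and sequenced section by section, and the deposited tables of that series were analysed without its raw reads. Per the labels, section 1 is distal. The CEL-Seq series held 202 sections of 14 arms: N2 anterior 1 to 3 and posterior 1 to 3, and anterior 1, anterior 2, posterior 1 and posterior 2 of both JK2879 (gld-2 gld-1) and GC833 (glp-1(ar202)). Per the labels, N2 anterior 1 and posterior 1 were made with the CEL-Seq barcode set and all other sectioned arms with that of CEL-Seq2. The small RNA series held 71 sections of 5 N2 arms. Uncut N2 arms gave 2 CEL-Seq, 5 small RNA, 3 poly(A) and 2 total RNA libraries, the last from 100 and 200 ng of RNA.

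The mRNA tables hold estimated counts, as deposited by the authors, with 1 value per 3' end isoform of a gene and library. They are not whole where reads were shared between isoforms, and from the values no normalization had been applied. They list 27501 isoforms of 21678 genes (4284 genes with 2 or more isoforms) and 86 ERCC spike-in transcripts among sections, and 22018 genes among the uncut libraries. The small RNA files hold whole read counts per mature miRNA arm and precursor, as deposited by the authors, without normalization. A read that matches several precursors is listed under each of them. Per the submitters' processing notes, the tools were bcl2fastq 2.18.0.12, STAR 2.5.1b, bedtools 2.23.0, SAMtools, kallisto 0.43.1 and Bowtie2 2.3.3.1 with the builds ce11 and WBcel235. The notes do not say which tool made which table, nor whether reads were collapsed by unique molecular identifier. The section tables also hold 2 other columns made by the authors: a mark on sections they called dropouts, and a position in percent of the arm. From the values, that position is the section number minus 0.5, divided by the number of sections and times 100, plus an alignment shift given in the labels. A further table of uncut and summed miRNA counts was left out because it repeats the counts of the small RNA table.

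Isoform counts were summed per gene and rounded, and counts of 1 mature miRNA under several precursors were collapsed into a single value, which took 624 entries to 600 miRNAs (166 of them with names starting in nov). miRNAs of different names stayed apart also where their counts were identical in every library, which left 165 distinct among the 169 tested between regions. ERCC transcripts were left out of gene totals. Chromosomes came from the WBcel235 annotation. Printed positions of mRNAs are those of the counted 3' end isoforms (8890500 to 8890999 for oma-1), not of whole genes. Deposited starts lay 2 bases below those of the annotation, with equal ends, so 2 was added. Sections of 1 arm are not replicates. Each arm was therefore divided into 3 equal regions of its section positions, without the alignment shift, and counts were summed per arm and region or per whole arm. All sections were used, dropouts included. The arm or the library was the replicate throughout.

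Tests used edgeR 4.0.16 in R 4.3.3: TMM scaling, the filterByExpr filter, quasi-likelihood fits and tests, and a Benjamini-Hochberg threshold of 0.05. An adjusted p in the text is from this test unless camera, limma, DESeq2 or the Simes test is named. Regions of N2 arms were compared with the arm as a block. Regional changes in the mutants, and their differences from N2 as interaction terms, were fitted in all 14 arms with 1 shared spread. Whole arms were fitted together with arm side as covariate. Sides were compared in N2 arms alone. Use of 3' ends was tested with diffSpliceDGE and the Simes method at gene level. Uncut small RNA libraries were described by mean and SD. Lists were tested with camera (limma 3.58.1, prior count 2, correlation 0.01), adjusted over the lists of a comparison, and with an estimated correlation and with fry as checks. Within a list, the genes passing genome-wide and those passing when adjusted over the list alone were counted. Printed region and arm levels are CPM with TMM scaling, with SD over arms, levels in bins along the arm and in uncut small RNA libraries are CPM without it, and shares are percent of raw counts. Profiles along the arm used the authors' positions without dropout sections, in bins of 10%, averaged per arm and then over arms. A fold against a group without counts is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts, a ratio with its 95% interval is given, which covers counting error alone. Adjusted p measure the spread between these arms, part of which may be technical.

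These comparisons, tests, lists and names were chosen before the data were examined. The gene lists were GLP-1/Notch targets and distal progenitor regulators, germline RNA regulators, DNA replication, M phase, meiotic prophase, oocyte maturation and eggshell, maternal polarity and embryonic fate, reported GLD-1 targets, sperm, P granule and germline small RNA pathways, cytosolic ribosomal proteins, replication-dependent histones, mitochondrially encoded, heat shock, apoptosis and engulfment, and X-linked genes. Markers of other cell types formed 6 more lists (sheath and spermatheca, distal tip cell, body wall muscle, intestine, hypodermis and cuticle, neurons). For miRNAs, 10 lists held the mir-35, let-7, mir-51, mir-58, mir-44 and mir-61, mir-2 and mir-43, mir-63 to mir-66, mir-72 to mir-74 and lin-4 families and miRNAs reported from somatic tissues. Genes share lists: puf-5, oma-1, lin-41 and mex-3, for example, stand in 3 or more. The genes to name were the 10 with the largest changes in each direction among those past the threshold, with a mean of at least 10 CPM and the same direction in every arm or ranges that did not overlap. To these were added up to 4 members of each list by smallest p with examples that did not pass, a fixed set of 16 germline genes, the msp genes as a group, miRNAs of the families at 10 CPM or more and the 10 most abundant miRNAs.

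Dropout sections had a median of 11723 counts with 31.5% from ERCC transcripts, against 0.848% in the other 165 sections. Across genes, which are not independent replicates, rank correlations between arms of 1 genotype and side ran from 0.830 to 0.953. In simulated counts with the depth of these libraries, 100 genes were given 4-fold and 100 were given 16-fold changes. All genes had 1 common spread and all libraries 1 pooled profile, without differences between arms, so recovery and false calls in the real counts may differ. Between the end regions of N2 arms 62 and 99 were recovered, and between middle and outer regions 77 and 98. Along gld-2 gld-1 arms 14 and 87 were recovered, along glp-1(ar202) arms 21 and 91, and for the 2 interaction terms 5 and 59 (gld-2 gld-1) and 5 and 52 (glp-1(ar202)). For whole arms the values were 2 and 66 (gld-2 gld-1 against N2), 0 and 70 (glp-1(ar202) against N2), 3 and 44 (between the mutants) and 6 and 83 (N2 sides), and for poly(A) against total RNA 0 and 0. For miRNAs 4 and 10 of 15 were recovered between end regions, 9 and 14 of 15 between middle and outer regions, and 0 and 0 of 15 between sides. For 3' ends 8 and 41 of 50 were recovered. Between 0 and 10 unchanged genes were called in each comparison.

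The alternatives tried were size factors or the Wald test of DESeq2 1.42.0, no filter on low counts, 4 parts of an arm in place of 3, with the outer 2 compared, no arm block or a block on the replicate number, sections weighted equally (limma on log2 of CPM plus 1), sections under 10000 counts (small RNA: under 1000) left out, the labelled shift added or subtracted, the 2 arms of the earlier barcode set left out, and each arm or library left out in turn. For 3' ends they were the F test and a minimum of 10 counts, and for the uncut small RNA libraries TMM scaling. Leaving out dropout sections, with and without the labelled shift, was added after the data were seen. Tables were handled with the package data.table (1.17.8), pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9 in Python 3.11.15.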

Results

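Gene expression was followed along single gonad arms of young adult Caenorhabditis elegans hermaphrodites, in which germ cells divide at the distal end and oocytes form at the proximal end. Arms were frozen and cut into sections 50 micrometres thick, numbered from the distal end. CEL-Seq, which counts the 3' ends of polyadenylated RNA, gave 202 section libraries from 14 arms. These were 6 arms of the wild type N2 (3 anterior and 3 posterior), 4 arms of strain JK2879, labelled gld-2 gld-1, and 4 arms of strain GC833, labelled glp-1(ar202). Small RNA libraries came from 71 sections of 5 N2 arms (3 anterior and 2 posterior) and from 5 uncut N2 anterior arms. Uncut N2 anterior arms also gave 3 poly(A)-selected and 2 total RNA libraries, and uncut N2 arms gave 2 CEL-Seq libraries, 1 from each side. Each arm was divided by length into 3 equal regions, called distal, middle and proximal here, and the counts of each region were summed. These names follow section numbers, without the alignment shifts of the labels, and do not mark the same place in every arm. By the authors' positions, the proximal region of N2 posterior arm 1 lay between 43% and 69.7% of the arm. The distal region of N2 anterior arm 3 began at 16.6%. Depth per mRNA section ran from 2676 to 10835590 counts (median 1060138), and per whole arm from 4667701 to 40358120. The mRNA arms had 24841 to 13869610 counts in distal, 3900837 to 18727480 in middle and 742024 to 21405280 in proximal regions. The authors called 37 of the 202 mRNA sections dropouts, of which 33 lay in distal regions, and in 3 arms every section of the distal region was called so. Small RNA sections held up to 572133 counts (median 11853), small RNA arms 145416 to 1048318, and uncut small RNA libraries 26394 to 149445. The uncut CEL-Seq libraries held 2338643 and 4666579 counts, and the poly(A) and total RNA libraries 55342820 to 89532867.

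**Figure D1:**
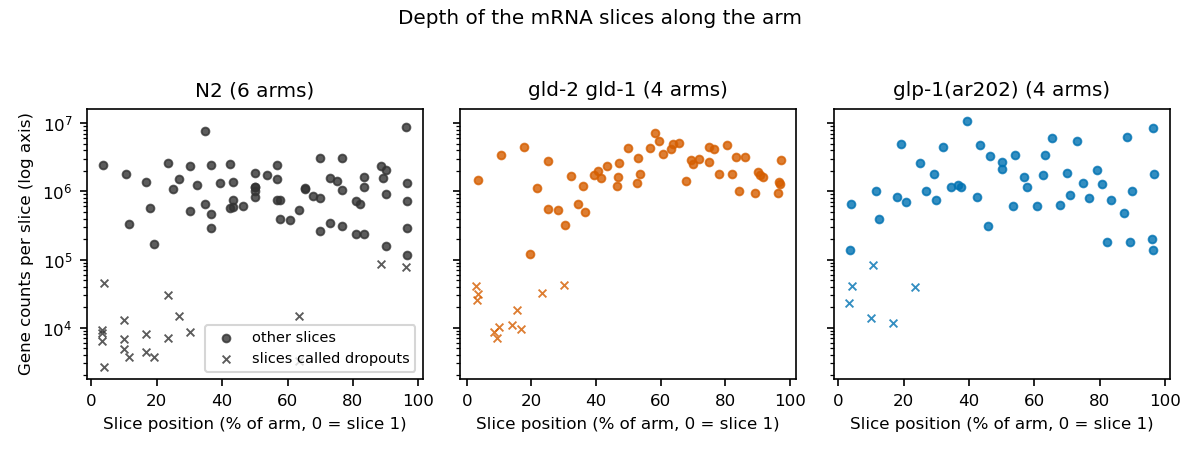
Gene counts per mRNA section (log axis) against section position in percent of the arm, counted from the distal end, for 6 N2, 4 gld-2 gld-1 and 4 glp-1(ar202) arms. Crosses are the 37 sections the authors called dropouts, of which 33 lie in the distal region of an arm, and circles are the other 165.

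The proximal region of the N2 arms was compared with the distal region to ask which mRNAs differ between the opposite ends of the gonad. X-linked mRNAs were higher in the proximal region and mRNAs for cytosolic ribosomal proteins were lower. The gene with the largest rise was cdr-4, whose counted 3' end region lies on chromosome V (12407429 to 12408132, WBcel235). It stood at 0.187 ± 0.238 CPM in distal, 12.7 ± 13.9 in middle and 39.8 ± 52.1 in proximal regions (SD, n = 6), a log2 fold change of 5.86 (SE 0.99). The X-linked genes tag-294 (3' end region X, 5760281 to 5760780) and tth-1, which encodes a thymosin repeat protein, rose by log2 5.83 and 5.22, tth-1 from 2.31 ± 3.63 to 69.5 ± 70.8 CPM. On the X chromosome, mrp-5, a heme transporter gene, and sec-22, a vesicle SNARE gene, rose by log2 5.21 and 5.39. The autosomal agxt-1, Y57G7A.2 and sdz-37 rose by 5.31, 5.64 and 5.21. C14B1.7 had the largest fall, from 92.1 ± 77.5 to 8.49 ± 4.98 CPM (log2 -3.27, SE 0.56). For rpl-15 of the large ribosomal subunit the fall was from 4537 ± 1689 to 1025 ± 915 CPM (log2 -2.86, SE 0.71). Each of these genes moved the same way in 6 of 6 arms, with edgeR adjusted p from 0.00016 (tth-1) to 0.00901 (rpl-15). In anterior arm 2 and posterior arm 1, every section of the distal region (24841 and 45322 counts) was called a dropout, so their direction is less certain.

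The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 1547 of 7387 genes, 1284 higher and 263 lower in proximal regions, and 831 of them moved the same way in all 6 arms. The median of all tested genes lay at log2 0.32, and at 0.60 with the size factors of DESeq2. Without anterior arm 1, anterior arm 3 or posterior arm 3 the count was 630, 767 or 467. It was 801 without the arms made with the earlier CEL-Seq barcode set (anterior 1 and posterior 1). Without dropout sections and with the shift of positions given in the labels, a setting added after the data were seen, 4077 genes passed, 2142 of them higher.

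Among the lists fixed beforehand, that of maternal polarity and embryonic fate genes had 8 of 26 members higher and 0 lower (12 and 0 when adjusted over the list alone), with a median log2 of 1.06. Without posterior arm 1 the median was 0.699. All 26 had a positive fold change. Camera gave an adjusted p of 0.0429 (adjusted p = 0.98 with an estimated correlation). Its member cdc-25.3, a phosphatase gene of the CDC25 family, rose from 14.6 ± 18.2 to 195 ± 79.0 CPM (log2 3.89, edgeR adjusted p = 0.00016, 6 of 6 arms). Likewise nos-2, a Nanos gene whose maternal mRNA acts in embryonic germ cells, rose from 153 ± 126 to 586 ± 189 CPM (log2 2.16, edgeR adjusted p = 0.0185). Of the oocyte maturation and eggshell list, 8 of 23 members rose and 0 fell (12 and 0 adjusted over the list alone; median 1.13; camera adjusted p = 0.31). They included puf-5, an oocyte regulator of translation (193 ± 132 to 512 ± 201 CPM, log2 1.53), oma-1, needed for oocyte maturation (63.9 ± 41.4 to 198 ± 107 CPM, log2 1.64), and the eggshell gene perm-4 (log2 2.78). Of 18 reported GLD-1 target mRNAs, 6 rose and 0 fell (13 and 0 adjusted over the list alone; median 1.28; camera adjusted p = 0.203); lin-41 (log2 1.62) and mex-3 (log2 1.54) were among them. The yolk receptor gene rme-2 (log2 0.92, edgeR adjusted p = 0.152), oma-2 (0.91), mex-5 (1.05) and pos-1 (1.26) did not pass. Leaving out anterior arm 1 ended the calls of nos-2, puf-5, oma-1, perm-4, lin-41 and mex-3 (edgeR adjusted p from 0.0535 to 0.182), and leaving out posterior arm 3 did the same (0.0655 to 0.147). The calls of oma-1, puf-5 and lin-41 also ended without anterior arm 3 (0.0625 to 0.0678), that of perm-4 without anterior arm 2 (0.0602), and those of lin-41 and mex-3 without posterior arm 2 (up to 0.119).

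Of the 12 genes of the list of GLP-1/Notch targets and distal progenitor regulators, 2 rose and 0 fell (4 and 1 adjusted over the list alone; median 0.64; camera adjusted p = 0.709). Beside mex-3 this was sygl-1 (3' end region on chromosome I, 12485062 to 12486469), a direct target of GLP-1 signalling, which reached 219 ± 64.5 CPM in proximal regions (log2 1.33, SE 0.48, edgeR adjusted p = 0.0485, 6 of 6 arms). Leaving out any one of the 6 arms ended that call (edgeR adjusted p = 0.0514 to 0.261). The other target lst-1 (log2 0.95), the receptor gene glp-1 (1.21, edgeR adjusted p = 0.0556) and the PUF genes fbf-1 (0.04) and fbf-2 (-1.18) did not pass. The germline RNA regulators had 7 of 25 members higher and 0 lower (8 and 1 adjusted over the list alone; median 0.71; camera adjusted p = 0.924), and gld-1 (-0.10; 0.18 with the size factors of DESeq2, which turned its sign) and gld-2 (-0.26) did not pass. For DNA replication the counts were 2 of 30 higher and 0 lower (1 and 0 adjusted over the list alone; median 0.51; camera adjusted p = 0.937), and for M phase 1 of 23 and 0 (0 and 0; median 0.20, against a camera test that pointed down with an adjusted p of 0.396). For meiotic prophase, 1 of 36 genes fell, htp-1 of the chromosome axis (246 ± 42.5 to 133 ± 44.8 CPM, log2 -1.05, edgeR adjusted p = 0.0383), and 0 rose (0 and 0 adjusted over the list alone; median -0.20; camera adjusted p = 0.126). The call of htp-1 ended without anterior arm 1, anterior arm 3, posterior arm 2 or posterior arm 3 (edgeR adjusted p = 0.108 to 0.142). The synaptonemal complex gene syp-1 (-0.68) did not pass. Nor did the axis gene him-3 (0.02), which fell by log2 -0.78 with the labelled shift of positions (edgeR adjusted p = 0.0239, and 0.012 to 0.995 over all its alternatives).

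By finer position, with dropout sections left out and the positions as the authors give them, sygl-1 mRNA in N2 stood at 102 ± 89.9 CPM between 10 and 20% of the arm (6 arms), 40.9 ± 55.1 between 20 and 30% (6 arms) and 359 ± 188 between 80 and 90% (4 arms). For gld-1, whose protein represses translation in early meiosis, the levels were 218 ± 104 CPM between 10 and 20%, 118 ± 64.4 between 40 and 50% (6 arms) and 436 ± 157 between 80 and 90% (4 arms). In gld-2 gld-1 arms, sygl-1 stood at 86.5 ± 66.4 CPM between 10 and 20% (2 arms) and 13.7 ± 8.31 between 20 and 30% (4 arms). These levels were not tested bin by bin.

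**Figure D2:**
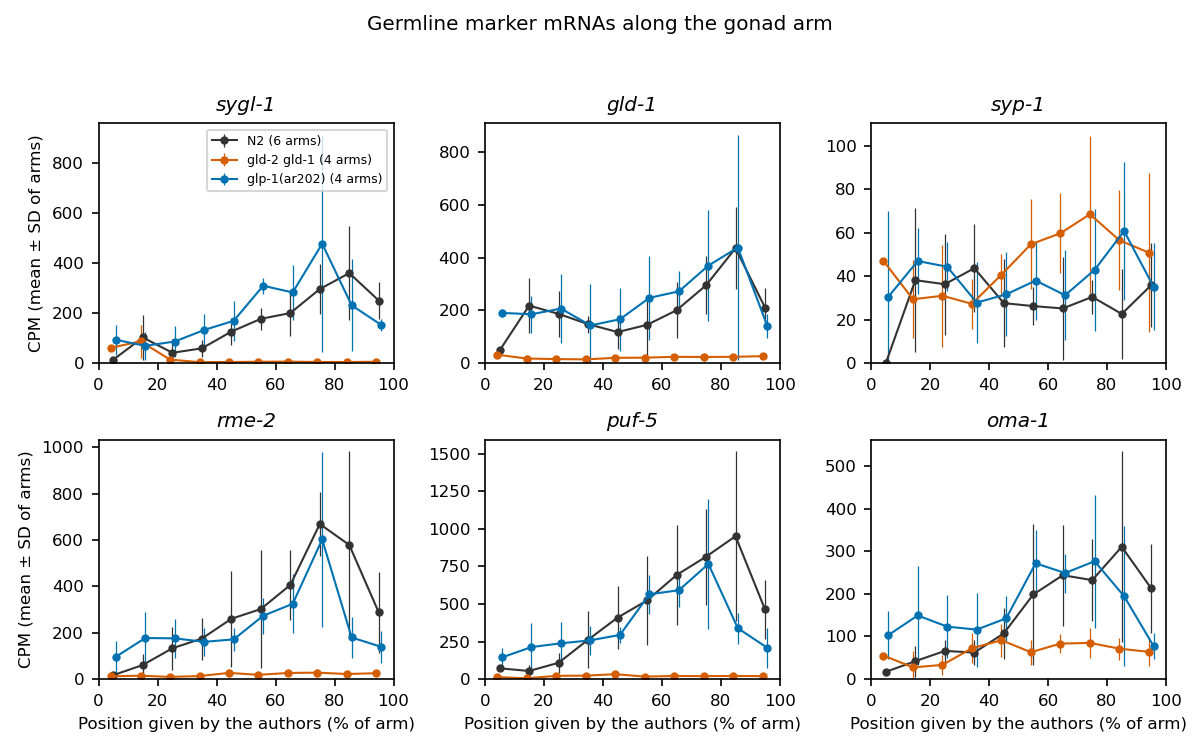
CPM of 6 germline mRNAs along the gonad arm, in bins of 10% of the position given by the authors with dropout sections left out; points are means over arms, bars are SD, and colours are the 3 genotypes. For sygl-1 the bins between 10 and 20% and between 20 and 30% stand at 102 and 40.9 CPM in N2 and at 86.5 and 13.7 CPM in gld-2 gld-1 arms.

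Of 741 tested X-linked genes, 470 were higher and 4 lower in proximal regions (591 and 11 adjusted over the list alone), 713 had a positive fold change, and the median log2 was 3.53, also with genes without counts in a group set to their bound. Camera gave an adjusted p of 3.53e-32 for the list (adjusted p = 0.29 with an estimated correlation). Examples were F53H4.2 (20.8 ± 41.5 to 324 ± 308 CPM, log2 5.41, edgeR adjusted p = 0.000154), Y62H9A.3 (log2 5.39), the chaperone gene hsp-3 (log2 3.16) and rpl-11.2 (log2 3.04), which is X-linked, while most ribosomal protein genes are autosomal. A few loci held most X-linked counts: 10 genes had 72.6% of those in N2, and the locus with the most, F59D12.1, had 38020 ± 25670 CPM in distal and 22550 ± 20400 in proximal regions. Without these 10 genes the X-linked share of N2 counts was 0.906% ± 0.575 in distal, 1.29% ± 0.834 in middle and 3.69% ± 1.61 in proximal regions (n = 6). The share of all X-linked genes was 8.82% ± 5.85 in distal and 9.32% ± 4.26 in proximal regions. Over whole arms it was 3.66% and 2.52% in the arms of the earlier barcode set and 7.83% to 11.5% in the other N2 arms.

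Of 78 tested cytosolic ribosomal protein genes, 66 fell and 2 rose (73 and 2 adjusted over the list alone; median log2 -2.28; camera adjusted p = 1.24e-74, adjusted p = 0.282 with an estimated correlation). Their share of N2 counts was 34.0% ± 4.42 in distal, 28.1% ± 14.7 in middle and 12.6% ± 8.74 in proximal regions (n = 6). Falls of rps-22 (5359 ± 1422 to 1566 ± 1658 CPM, log2 -2.70) and rpl-1 (log2 -2.59) had edgeR adjusted p of 0.0123 and 0.0114. Without posterior arm 3, rpl-15, rps-22 and rpl-1 no longer passed (edgeR adjusted p = 0.0562, 0.0691 and 0.0657). In the P granule and germline small RNA list, 4 of 30 genes fell and 0 rose (4 and 0 adjusted over the list alone; median -0.15, from -0.478 without posterior arm 1 to -0.0392 without posterior arm 3; camera adjusted p = 0.0153, adjusted p = 0.98 with an estimated correlation). They were the Argonaute gene csr-1 (141 ± 49.9 to 54.4 ± 32.5 CPM, log2 -1.54, edgeR adjusted p = 0.00856, 6 of 6 arms), the Argonaute genes wago-4 (-1.52) and ppw-2 (-1.20), and the helicase gene glh-1 (-1.87). With sections weighted equally, glh-1 turned to 0.18 (limma adjusted p = 0.871). The call of glh-1 ended without anterior arm 1 or posterior arm 3 (edgeR adjusted p up to 0.0894). That of wago-4 ended without anterior arm 3, posterior arm 2 or posterior arm 3 (up to 0.0846), and that of ppw-2 without any of these or anterior arm 1 (up to 0.117). None of 12 mitochondrially encoded genes passed singly (0 and 0 adjusted over the list alone), with a median of -0.43 (from -1.09 without anterior arm 2 to -0.141 without posterior arm 3) and a camera adjusted p of 5.56e-05 (adjusted p = 0.971 with an estimated correlation).

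Single markers of other cell types were higher in proximal regions, though camera called none of the marker lists. Of 7 gonadal sheath and spermatheca genes, 5 rose and 0 fell (6 and 0 adjusted over the list alone; median 2.99; camera adjusted p = 0.0608), among them the gap junction gene inx-8 (41.5 ± 38.9 to 211 ± 96.9 CPM, log2 2.55) and its paralogue inx-9 (log2 2.99). Of 9 body wall muscle genes 3 rose (5 adjusted over the list alone; median 1.78; camera adjusted p = 0.203), with the actin gene act-4 at log2 2.54 (5 of 6 arms), a call that ended without posterior arm 3 (edgeR adjusted p = 0.0545). Of 14 intestinal genes 4 rose (7 adjusted over the list alone; median 2.60; camera adjusted p = 0.933), with the protease gene cpr-4 at log2 3.72, a call that ended without posterior arm 3 (edgeR adjusted p = 0.0523). Hypodermis and cuticle had 2 of 16 higher and 1 lower (2 and 1 adjusted over the list alone; median 0.63, against a camera test that pointed down with an adjusted p of 0.387), and neurons 1 of 5, unc-119 (1 adjusted over the list alone; median 1.02; camera adjusted p = 0.564). The distal tip cell list had 1 tested gene, the netrin receptor gene unc-5 (log2 1.62), and it did not pass. The markers of these cell types together held 0.150%, 0.0632% and 0.364% of N2 counts in distal, middle and proximal regions, with 1.11% in the proximal region of anterior arm 3. In anterior arm 2 and posterior arm 1 their share was higher in the distal than in the proximal region. Replication-dependent histone genes rose in 8 of 29 cases and fell in 0 (8 and 0 adjusted over the list alone; median 0.40; camera adjusted p = 0.187). Copies of these genes are near identical, so their reads are hard to assign to one gene. Their mRNAs lack a poly(A) tail while CEL-Seq counts polyadenylated RNA, so these counts need not follow their levels. Heat shock (1 of 11 higher; 1 adjusted over the list alone; median 0.25, camera down, adjusted p = 0.543), apoptosis and engulfment (0 of 13; 0 adjusted over the list alone; median 0.62; camera adjusted p = 0.813) and sperm (1 of 5 higher, ssp-37; 1 adjusted over the list alone; median 0.05, camera down, adjusted p = 0.933) completed the lists. Transcripts of the 27 msp genes for major sperm protein made up 1.81e-05% of N2 section counts.

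**Figure D3:**
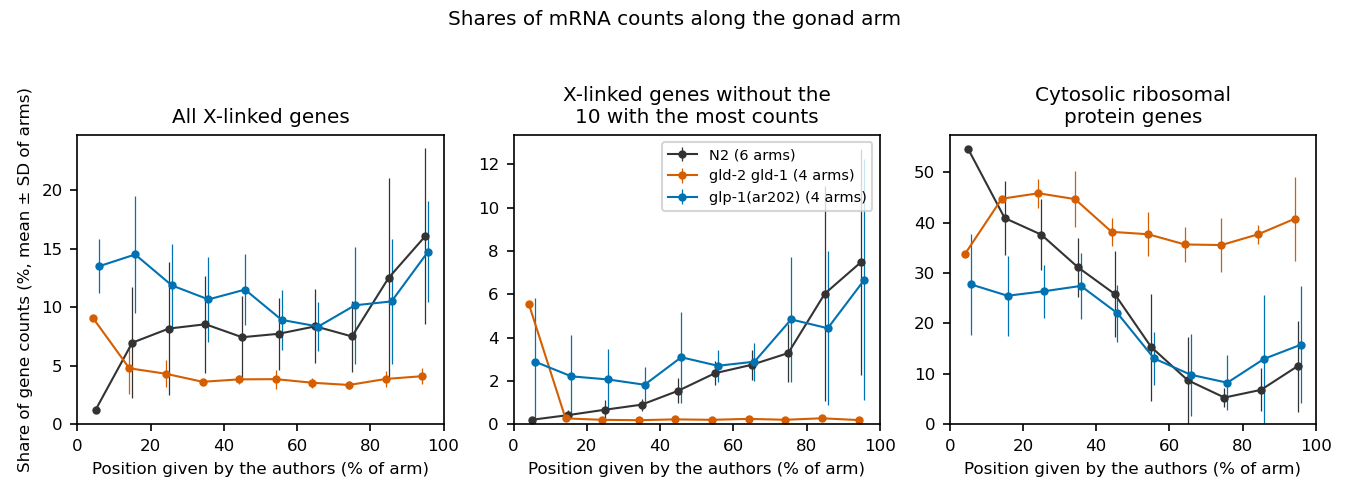
Shares of mRNA counts in percent (mean over arms, bars SD) for all X-linked genes, X-linked genes without the 10 that hold the most counts, and cytosolic ribosomal protein genes, in bins of 10% of the position given by the authors with dropout sections left out. Without the 10 genes, the X-linked share in N2 goes from 0.417% between 10 and 20% of the arm to 7.50% in the last bin, and in gld-2 gld-1 arms it is 0.185% there. The last bin also holds N2 anterior arm 3 sections at 102% and 109%.

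The middle region of N2 arms was compared with the mean of the outer regions. By the authors' positions it began at 9.67% of the arm in posterior arm 1 and at 52.3% in anterior arm 3, so it is not the same place in each arm. Lower in the middle were the X-linked Y62H9A.5, at 194 ± 364 CPM in distal, 110 ± 222 in middle and 2445 ± 1901 in proximal regions (log2 -3.67, edgeR adjusted p = 0.015), and ule-5, at 157 ± 249, 90.4 ± 157 and 2036 ± 1617 CPM (log2 -3.16). The autosomal Y37D8A.19 (log2 -3.71), F55B11.3 (-3.52) and the transthyretin-related gene ttr-2 (-3.20) were lower as well, each in 6 of 6 arms. The meiotic genes him-3 (232 ± 52.6 CPM in the middle, log2 0.61) and syp-1 (0.03) did not pass. The edgeR test called 16 of 7387 genes, 0 higher and 16 lower, and 204 genes had an unadjusted p under 0.05. All tested genes had a median of 0.15, and of 0.03 with the size factors of DESeq2, which called 8 genes. Without anterior arm 3 or posterior arm 3 the count was 0, without anterior arm 2 it was 2 and without posterior arm 1 it was 27. With the labelled shift of positions it was 307, and without dropout sections it was 0. Of the lists, camera called body wall muscle (median -1.53, adjusted p = 4.22e-15, adjusted p = 0.0384 with an estimated correlation) and hypodermis and cuticle (median -1.50, -0.872 without anterior arm 1, adjusted p = 6.08e-11, adjusted p = 0.0462 with an estimated correlation) lower in the middle. Genome-wide, 0 and 0 of their members were called (5 and 3 lower adjusted over the list alone). Intestine (median -1.70, adjusted p = 4.22e-15; adjusted p = 0.0935 with an estimated correlation; 0 called, 1 lower adjusted over the list alone) pointed the same way. The X-linked list had 8 of its genes lower and 0 higher (12 and 0 adjusted over the list alone) and a camera test that pointed down (adjusted p = 1.01e-23, adjusted p = 0.215 with an estimated correlation), beside a median of 0.01 (from -0.609 without anterior arm 1 to 0.352 without posterior arm 1).

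The arms labelled gld-2 gld-1, in which germ cells form a tumour in place of oocytes, were compared with N2 over whole arms. The mRNAs of both mutated genes were lower: gld-1 ran from 21.2 to 32.5 CPM in the 4 mutant arms, all under the lowest of the 6 N2 arms, whose mean was 180 ± 57.2 CPM (log2 -2.66, SE 0.34, edgeR adjusted p = 5.53e-05). For gld-2 the ranges were 5.15 to 14.4 and 6.20 to 51.1 CPM (log2 -1.75, SE 0.49, edgeR adjusted p = 0.0166). That call ended without gld-2 gld-1 anterior arm 1 or 2 (edgeR adjusted p = 0.0631 and 0.0552) and without the arms of the earlier barcode set (0.0514). The labels do not say which part of either gene is altered, so the counted 3' ends are no test of the alleles. Several oocyte and embryonic fate mRNAs were lower: nos-2 at 5.63 ± 2.04 against 445 ± 129 CPM (SD, n = 4 and 6; log2 -6.30), cdc-25.3 at 0.510 ± 0.338 against 102 ± 16.6 CPM (log2 -7.62), the eggshell gene cpg-3 at 12.1 ± 4.34 against 1256 ± 780 CPM (log2 -6.70). Likewise lower were puf-5, at 24.4 ± 9.83 against 390 ± 174 CPM, and the yolk receptor gene rme-2, at 26.8 ± 8.34 against 273 ± 149 CPM (log2 -3.35). For these 5 genes the edgeR adjusted p ran from 1.03e-08 (cdc-25.3) to 8.59e-05 (rme-2). Of the progenitor list, sygl-1 stood at 13.6 ± 15.5 against 134 ± 33.5 CPM (log2 -3.35, edgeR adjusted p = 0.00139). It was at 36.8 CPM in posterior arm 2 of the mutant and at 5.01 to 6.46 in the other arms, and the log2 value without that arm was -4.64. Posterior arm 2 had 0 dropout sections. Anterior arm 1, anterior arm 2 and posterior arm 1 of the mutant had 5, 3 and 3, all in distal regions, so distal sygl-1 mRNA may be missing from them. The other target lst-1 was lower too (log2 -1.28). Higher were fbf-1 (1.24) and fbf-2 (1.22), and fbf-2 lost its call without any of 8 arms (edgeR adjusted p up to 0.115, without gld-2 gld-1 posterior arm 2) and with the size factors of DESeq2.

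Higher in gld-2 gld-1 arms were F58D5.5, at 232 ± 103 against 13.0 ± 5.56 CPM (log2 4.09, edgeR adjusted p = 2.57e-05), nstp-6 (log2 4.09) and the filamin gene fln-1, at 624 ± 178 against 102 ± 51.8 CPM (log2 2.65). The germline RNA helicase gene cgh-1, at 1017 ± 217 against 271 ± 88.3 CPM (log2 1.93), and the Argonaute genes ppw-2 (log2 2.53) and csr-1 (log2 1.18) were higher as well. X-linked genes made up many of the lowest. W06D11.3 had 0.194 ± 0.0916 against 102 ± 30.1 CPM (log2 -8.97, edgeR adjusted p = 6.28e-09), and K04C1.5, Y75D11A.3 and F19H6.4 had log2 -9.65, -9.89 and -10.1. The X-linked forkhead gene fkh-3 and chitinase gene cht-1 had 0 counts over the 4 mutant arms and were at least 823-fold and 599-fold lower, against a floor of 3 counts over the group. With 1 count, the autosomal skr-7, a Skp1-related gene, had an N2 to mutant ratio of 17650 (95% counting interval 3168 to 697300). The test called 2712 of 11333 genes, 1128 higher and 1584 lower, and 1900 of them had ranges that did not overlap between groups. Over all 11333 genes, called or not, ranges did not overlap in 2302 (20.3%), against 0.952% with arms assigned at random. Over all genes the median moved from 0.02 to -0.17 with the size factors of DESeq2, which called 783 higher and 1809 lower. Without the earlier barcode set the count was 2272.

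By list, 15 of 23 oocyte maturation and eggshell genes were lower and 0 higher (15 and 0 adjusted over the list alone; median log2 -1.48; camera adjusted p = 2.31e-08, adjusted p = 0.857 with an estimated correlation), with gna-2 at log2 -4.32 and egg-1 at -3.74. For maternal polarity and embryonic fate the counts were 12 of 26 lower and 2 higher (median -0.66; camera adjusted p = 0.00179), and for GLD-1 targets 6 of 18 lower and 1 higher (6 and 3 adjusted over the list alone; median -0.61; camera adjusted p = 0.0293), both with an adjusted p = 0.857 with an estimated correlation. The median of GLD-1 targets was -0.404 without N2 anterior arm 1. The oocyte genes oma-1 (log2 -0.58), oma-2 (-0.29) and lin-41 (-0.74) did not pass. Of 1392 X-linked genes, 531 were lower and 0 higher (590 and 1 adjusted over the list alone; median -2.71, also with genes without counts at their bound; camera adjusted p = 2.52e-25, adjusted p = 0.857 with an estimated correlation). Without gld-2 gld-1 posterior arm 2 this median was -4.65. Cytosolic ribosomal protein genes were higher in 15 of 78 cases and lower in 0 (15 and 0 adjusted over the list alone; median 0.99; camera adjusted p = 1.92e-09, adjusted p = 0.857 with an estimated correlation), and they made up 36.7% ± 3.87 of counts in proximal regions of mutant arms. In meiotic prophase 6 of 36 genes were higher and 1 lower (5 and 1 adjusted over the list alone; median 0.37; camera adjusted p = 0.122), with chk-2 (1.25) and him-17 (1.02) higher and lab-1 lower (-3.78). Of the P granule list 8 of 30 were higher and 2 lower (11 and 2 adjusted over the list alone; camera adjusted p = 0.0541), and of 12 mitochondrially encoded genes 1 was higher (ctc-3, log2 1.18; camera adjusted p = 0.0293, adjusted p = 0.857 with an estimated correlation). Of the sheath list 1 of 16 was higher (fln-1) and 2 lower, with inx-8 at 16.6 ± 1.95 against 113 ± 64.3 CPM (log2 -2.76), and in the muscle, intestine, neuron and distal tip cell lists 0 genes passed. Hypodermis and cuticle had 2 of 47 lower and 0 higher (0 and 0 adjusted over the list alone) beside a median of 2.52 (-1.68 without gld-2 gld-1 posterior arm 2) and a camera test that pointed up (adjusted p = 0.0334, adjusted p = 0.857 with an estimated correlation).

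**Figure D4:**
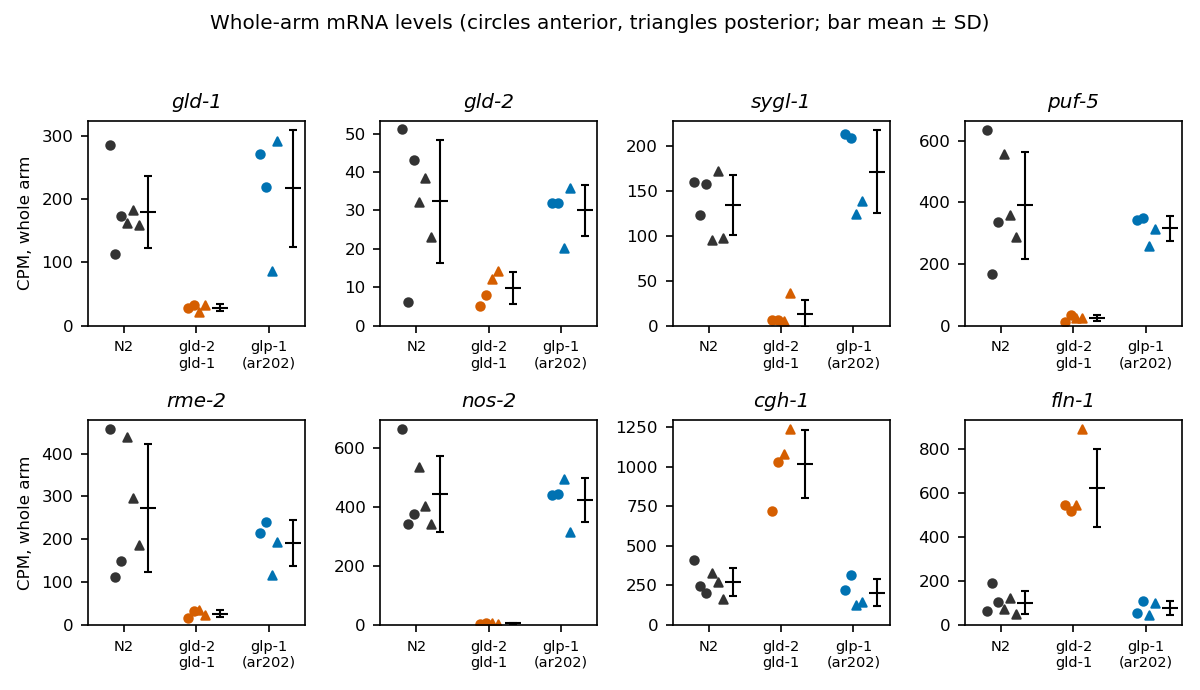
Whole-arm CPM of 8 genes in 6 N2, 4 gld-2 gld-1 and 4 glp-1(ar202) arms; circles are anterior and triangles posterior arms, and the bar is the mean with its SD. The 4 gld-2 gld-1 arms lie between 21.2 and 32.5 CPM for gld-1 and have a mean of 5.63 CPM for nos-2, against 445 CPM in N2.

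The arms labelled glp-1(ar202) carry a gain-of-function allele of the Notch receptor gene. Signalling by this receptor keeps germ cells dividing, but whether germ cells divided more in these arms than in N2 was not tested. Of the germline genes none passed the test against N2 over whole arms. The levels were, for sygl-1, 171 ± 46.0 against 134 ± 33.5 CPM (log2 0.36, SE 0.49, edgeR adjusted p = 0.811), for glp-1 50.8 ± 19.4 against 40.4 ± 12.8 CPM (log2 0.34), for gld-1 217 ± 92.7 against 180 ± 57.2 CPM (log2 0.27) and for puf-5 316 ± 40.8 against 390 ± 174 CPM (log2 -0.30). Ranges did not overlap in 192 of 11333 genes (1.69%), which chance gives in 0.952% of genes. Among them were those of fog-1, a gene of male germ cell fate, at 40.9 ± 12.1 against 14.2 ± 4.15 CPM (log2 1.52, edgeR adjusted p = 0.402), and the maternal gene spn-4, at 629 ± 146 against 361 ± 82.3 CPM (log2 0.80, edgeR adjusted p = 0.411). Both passed with DESeq2. The edgeR test called 0 of 11333 genes, with 1115 at an unadjusted p under 0.05 and 79 called by DESeq2. Lists moved by camera: ribosomal protein genes were lower (median -0.63, adjusted p = 1.5e-22), intestinal markers higher (median 3.22, adjusted p = 0.000189) and X-linked genes higher (median 0.80, adjusted p = 9.86e-08), each with an adjusted p = 0.809 with an estimated correlation and 0 members called. Without glp-1(ar202) anterior arm 1 these medians were -0.368, 1.43 and 0.205, and that of ribosomal protein genes was -0.314 without N2 anterior arm 2 and -1.27 without glp-1(ar202) anterior arm 2. That of intestinal markers was 6.39 without N2 anterior arm 3. Within the 4 arms, 5 genes were lower in the proximal than in the distal region and 0 higher: ppw-2 (172 ± 22.9 to 46.0 ± 32.5 CPM, log2 -2.16), C14B1.7 (-3.05), fbxa-106 (-3.25), fbxa-114 (-2.15) and T26E3.7 (-1.98), each in 4 of 4 arms with an edgeR adjusted p of 0.0485. These calls ended with the size factors of DESeq2, which moved the median of all genes from 0.41 to 0.77, while the test of DESeq2 called 989. Without anterior arm 1, anterior arm 2 or posterior arm 1 there were 0 calls, and without posterior arm 2 there were 498. Ribosomal protein genes fell along these arms as a list (74 lower and 2 higher of 78 adjusted over the list alone, 0 genome-wide; median -1.66; camera adjusted p = 8.19e-48, adjusted p = 0.487 with an estimated correlation). X-linked genes were higher in the proximal region (median 2.09, 1238 of 1307 positive, 0 called, 0 and 0 adjusted over the list alone; camera adjusted p = 4.12e-22, adjusted p = 0.487 with an estimated correlation). In posterior arm 2 the X-linked share without the 10 genes that hold the most N2 counts fell from 3.02% to 2.01%, and without this arm the median was 2.99, with 83 called higher and 2 lower. Markers of other cell types held 0.584% ± 0.559 of counts in distal and 2.31% ± 2.86 in proximal regions of the same arms, from 0.160% (posterior 2) to 6.46% (posterior 1). The difference from N2 in the change along the arm passed in 0 of 10710 genes by edgeR, with 319 at an unadjusted p under 0.05 and 6 called by DESeq2.

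Along gld-2 gld-1 arms the edgeR test called 0 of 10710 genes between distal and proximal regions, with 785 at an unadjusted p under 0.05 and 24 called by DESeq2. As lists, camera called intestine (median -3.58, adjusted p = 1.66e-10), hypodermis and cuticle (median -2.88, adjusted p = 1.26e-05) and mitochondrially encoded genes (median -1.05, adjusted p = 1.66e-10) lower in proximal regions. Each had 0 members called (7, 10 and 4 lower adjusted over the list alone) and an adjusted p = 0.55 with an estimated correlation. The first 2 medians rest on posterior arm 2, without which they were -1.74 and -0.798. Markers of other cell types held 2.80% of counts in its distal region and 0.0395% to 0.0676% in those of the other 3 arms. The change along the arm nonetheless differed from that in N2 for 218 genes, 23 with a larger and 195 with a smaller log2 value in the mutant, and 2683 had an unadjusted p under 0.05. For sygl-1, which was at 29.8 ± 30.2 CPM in distal and 5.25 ± 1.25 in proximal regions of mutant arms, the difference was log2 -3.85 (SE 0.75, edgeR adjusted p = 0.0123). X-linked genes such as mrp-5 (-7.26), the calumenin gene calu-1 (-6.33, edgeR adjusted p = 0.00636), and the autosomal aquaporin gene aqp-10 (-8.17), had negative differences. C14B1.7 (4.24) had a positive one. Of 1307 X-linked genes 89 had negative and 0 positive differences (392 and 2 adjusted over the list alone; median -5.09; camera adjusted p = 2.92e-24, adjusted p = 0.566 with an estimated correlation). Without gld-2 gld-1 posterior arm 2 this median was -1.98, with 0 called. The ribosomal protein list lay above all genes (0 called, 47 positive and 2 negative adjusted over the list alone; median 1.92; camera adjusted p = 1.11e-35, adjusted p = 0.566 with an estimated correlation). All tested genes had a median of -0.35, and of -0.91 with the size factors of DESeq2. Without a single arm the count fell to 40 (gld-2 gld-1 anterior 1), 29 (anterior 2), 47 (posterior 1), 1 (posterior 2), 43 (N2 anterior 1), 54 (N2 anterior 3) or 30 (N2 posterior 3), or rose to 352 (N2 posterior 2), and without the earlier barcode set it was 59. Without gld-2 gld-1 posterior arm 2, whose distal region held 13869610 of the counts, sygl-1 no longer passed (edgeR adjusted p = 0.166), nor did C14B1.7 and calu-1 (0.133), mrp-5 (0.458) or aqp-10 (0.387).

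The direct comparison of whole arms of the 2 mutants called 2991 of 11333 genes, 1185 higher and 1806 lower in gld-2 gld-1. Lower were nos-2 (5.63 ± 2.04 against 425 ± 75.4 CPM, n = 4 and 4, log2 -6.23), cpg-3 (log2 -5.73), sygl-1 (13.6 ± 15.5 against 171 ± 46.0 CPM, log2 -3.71), puf-5 (-3.69) and gld-1 (-2.92). Higher were Y43B11AR.3 (141 ± 20.2 against 17.9 ± 7.79 CPM, log2 3.01, edgeR adjusted p = 2.94e-06), F49E11.2 (3.65), fln-1 (3.02) and cgh-1 (2.37). Ribosomal protein genes were higher in 64 of 78 cases and lower in 1 (76 and 2 adjusted over the list alone; camera adjusted p = 2.84e-21), mitochondrially encoded genes in 8 of 12 (11 adjusted over the list alone; camera adjusted p = 2.2e-05) and P granule genes in 10 of 30, with 1 lower (11 and 1; camera adjusted p = 5.78e-05). Oocyte genes were lower in 16 of 23 cases (median -1.38, camera adjusted p = 4.02e-06) and X-linked genes in 630 of 1392, with 1 higher (712 and 1 adjusted over the list alone; median -3.68, camera adjusted p = 2.41e-32), all with an adjusted p = 0.534 with an estimated correlation. Without gld-2 gld-1 posterior arm 2, which unlike the other arms of this mutant had 0 dropout sections, the X-linked median was -6.09 and sygl-1 was at -4.91. Over all genes the median was -0.28, and -0.51 with the size factors of DESeq2, which called 741 higher and 2032 lower. Without glp-1(ar202) posterior arm 1 the count was 1947.

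N2 posterior and anterior arms were compared to look for differences between the sides. The edgeR test called 0 of 8958 mRNAs (88 at an unadjusted p under 0.05, 2 by DESeq2). As a list, replication-dependent histone genes were lower in posterior arms (median -0.74; camera adjusted p = 4.31e-08, adjusted p = 0.92 with an estimated correlation). The median was 0.0653 without anterior arm 2, -0.367 without posterior arm 1 and -1.13 without posterior arm 2. These mRNAs lack the poly(A) tail that CEL-Seq relies on, so their counts need not follow their levels. For miRNAs, 7 of 235 were called, all lower in the 2 posterior than in the 3 anterior arms. Among them were miR-77-3p (35.8 ± 9.23 against 3577 ± 2835 CPM, log2 -6.63, edgeR adjusted p = 0.00162), miR-62 (log2 -6.60), miR-60-3p (-6.50), miR-63-3p (-6.34), miR-236-3p (-4.82) and miR-2-3p (-4.43), while miR-77-5p had 0 counts in posterior arms and was at least 13.5-fold lower. With the size factors of DESeq2 the count was 0, without anterior arm 2, posterior arm 1 or posterior arm 2 it was 0, and without anterior arm 3 it was 2. The median of all miRNAs moved from 0.17 to -0.03 under that scaling.

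In uncut N2 anterior arms the mir-35 family, which acts in the early embryo, held 53.1% ± 7.47 of miRNA counts (SD, n = 5), the mir-58 (bantam) family 12.0% ± 3.80, the mir-63 to mir-66 cluster 8.82% ± 1.55 and the mir-51 family 8.38% ± 0.862. The let-7 family held 2.38%, mir-44 and mir-61 1.77% (1.64% with the identical counts of miR-44-3p and miR-45-3p taken once), mir-2 and mir-43 0.752%, lin-4 0.179% and miRNAs reported from somatic tissues 0.805%. The most abundant miRNAs were miR-35-3p (chromosome II, 11537668 to 11537689), at 15.9% ± 4.46, and miR-40-3p at 15.1% ± 2.57, and the 10 most abundant together held 69.1% ± 7.46. Levels of miR-41-3p ran from 188 to 125400 CPM among the 5 libraries. Members of a family share much of their sequence, and the files list a read under each precursor it matches, so single members are less certain than families.

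Along N2 arms the mir-35 family held 6.27% ± 4.98 of miRNA counts in distal and 44.2% ± 18.5 in proximal regions (n = 5). Of its 15 tested members 13 were higher in proximal regions and 0 lower (median log2 2.70; camera adjusted p = 0.000531, adjusted p = 0.214 with an estimated correlation). Without posterior arm 1 the median was 1.77, with 8 higher. The largest differences were those of miR-42-3p (40.7 ± 61.7 to 6093 ± 5172 CPM, log2 7.50, edgeR adjusted p = 4.62e-06) and miR-35-3p (log2 6.61, SE 0.70, edgeR adjusted p = 1.27e-06), each in 5 of 5 arms. All 7 tested members of the mir-63 to mir-66 cluster rose (median 3.93; camera adjusted p = 0.00286, adjusted p = 0.214 with an estimated correlation), as miR-66-5p did by log2 3.92. In the bantam family 5 of 7 rose and 1 fell (camera adjusted p = 0.0949), with miR-82-3p at log2 5.17 and miR-58a-3p at 4.48. In raw counts the share of the mir-63 to mir-66 cluster was 4.17% in distal and 9.99% in proximal regions. That of the bantam family was 8.41% and 16.6%. The fold changes named for both, taken after TMM scaling, were larger than these changes of share, so the size of a rise depends on the scaling. In the mir-51 family 5 of 7 rose, with miR-52-5p at 4.07, and 1 fell, miR-51-3p, from 19180 ± 13370 to 3153 ± 2307 CPM (log2 -2.74; camera adjusted p of the family 0.1). The share of this family in the raw counts was 8.70% ± 4.35 in distal and 9.95% ± 5.35 in proximal regions. Of let-7 members 3 of 4 rose (camera adjusted p = 0.124), with miR-84-5p at 4.87 and let-7-5p not passing (1.33). The mir-44 and mir-61 family had 4 of 4 higher (camera adjusted p = 0.0949) after TMM scaling, but miR-44-3p and miR-45-3p have the same count in every library and are 1 measurement. With these counts taken once, its share in the raw counts was 2.80% ± 1.01 in distal and 1.53% ± 0.551 in proximal regions. Members also rose in mir-72 to mir-74 (3 of 4; camera adjusted p = 0.125), the lin-4 family (1 of 2; 0.558) and the somatic list (7 of 8; 0.0545), with the muscle miRNA miR-1-3p at 3.72. The mir-2 and mir-43 family went both ways, with miR-43-3p higher (5.61) and miR-250-3p lower (-1.15, a call that ended without posterior arm 2, edgeR adjusted p = 0.0731), while its share fell from 7.63% ± 2.28 to 1.09% ± 0.512 (camera adjusted p = 0.861). In all, 91 of 169 miRNAs passed (90 of 165 with identical counts taken once), 64 higher and 27 lower, among the latter nov-31-5p (log2 -2.94). Over all miRNAs the median was -0.14, and -0.42 with the size factors of DESeq2, which called 60 higher and 47 lower.

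**Figure D5:**
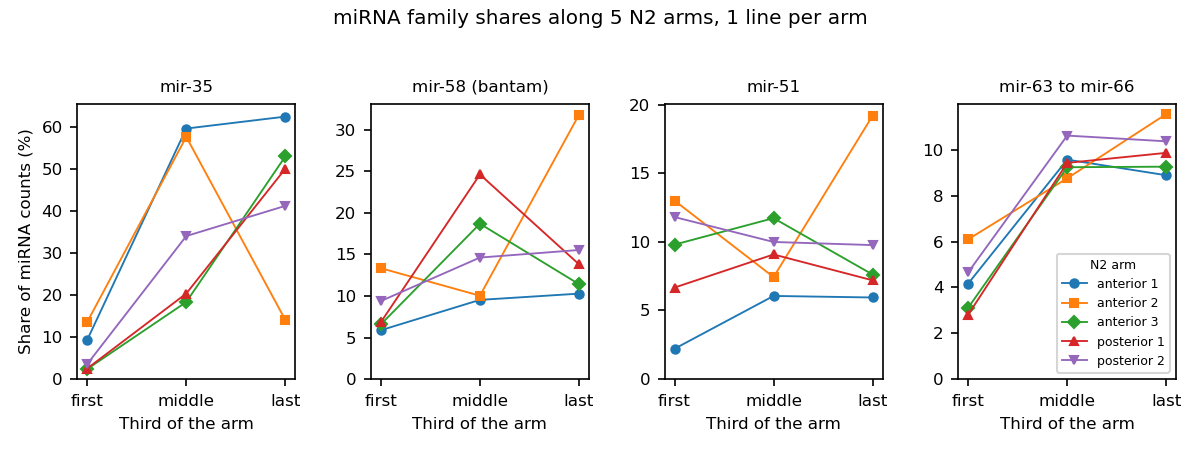
Share of miRNA counts in percent in distal, middle and proximal regions of 5 N2 arms, 1 line per arm, for 4 miRNA families. The mir-35 family goes from a mean of 6.27% in distal to 44.2% in proximal regions, and the lowest proximal region, that of anterior arm 2, stands at 14.1%.

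Between the middle and the outer regions, 30 of 169 miRNAs were lower in the middle and 0 higher, among them the neuronal miR-124-3p (1351 ± 1355 CPM in distal, 145 ± 101 in middle and 1752 ± 2718 in proximal regions, log2 -3.17), miR-237-5p of the lin-4 family (-3.26, edgeR adjusted p = 0.0264), miR-79-3p (-3.06) and miR-250-3p (-1.26). The mir-35 family had a median of 0.56 (1.16, 1.43 or 1.42 without anterior arm 1, anterior arm 3 or posterior arm 1; camera adjusted p = 0.000948, adjusted p = 0.724 with an estimated correlation). With the size factors of DESeq2, which moved the median of all miRNAs from -0.36 to 0.30, the count was 0, and without any one of anterior arm 1, anterior arm 3, posterior arm 1 or posterior arm 2 it was 0.

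Use of alternative 3' ends was compared between proximal and distal regions of N2 arms in 813 genes with 1716 tested isoforms. The gene otub-4 on chromosome IV, a deubiquitinase homologue, used its most downstream end for 96.0% ± 8.94 of counts in distal (n = 5) and 22.5% ± 24.9 in proximal regions (n = 6). Its most downstream end lies at position 3373387. It was the single gene called by edgeR's diffSpliceDGE (Simes adjusted p = 0.00933), and 35 genes had an unadjusted p under 0.05. Without anterior arm 1, posterior arm 2 or posterior arm 3 the count was 0. Its ends lie 7 bases apart, and otub-4 was chosen after its values were seen.

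Poly(A) selection and total RNA were compared in uncut N2 anterior arms. Replication-dependent histone mRNAs, which lack a poly(A) tail, were lower after selection. For his-66 the level was 16.9 ± 10.5 CPM after selection (n = 3) and 2461 ± 26.5 CPM in total RNA (n = 2). Over the histone list the median was log2 -5.51, with 0 genes called genome-wide and 46 of 56 lower when adjusted over the list alone. Camera gave an adjusted p of 3.46e-14 (adjusted p = 0.987 with an estimated correlation). Ribosomal protein mRNAs had a median of 1.40 and a positive fold change in 78 of 78 cases, with 0 called genome-wide and 0 adjusted over the list alone (camera adjusted p = 3.46e-14, adjusted p = 0.987 with an estimated correlation). The edgeR test called 0 of 12900 genes (2127 at an unadjusted p under 0.05, 1260 by DESeq2), and 8677 without poly(A) library 1. Across genes, which are not independent replicates, that library had a rank correlation of 0.922 and 0.924 with the total RNA libraries and of 0.825 and 0.819 with the other poly(A) libraries.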

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

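Of the tests below, those of dropout sections and positions, of genes that take most counts and of oocyte-forming germ cells for X-linked genes, that of other cell types between distal and middle regions, those of dropout sections and of oocyte-forming germ cells for sygl-1, and those over all members and on the count ratios of the mir-35 family were chosen after the results were seen.

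X-linked mRNAs were higher in proximal than in distal regions of N2 arms, with a median log2 of 3.53. Leaving out dropout sections and adding the labelled shift gave a median of 3.92, and the fall of the ribosomal share changes every other gene by a log2 factor of 0.405, so neither can be the whole cause. From distal to middle regions in that setting the median of 794 X-linked genes was 3.26, above that of 40 markers of other cell types (0.15 ± 1.66, 22 higher) by more than their spread, but above that of the 7 sheath and spermatheca markers (0.52 ± 2.97) by less than theirs. The share of all markers went from 0.0479% to 0.0886%, that of X-linked counts from 7.65% to 7.28%, and that of X-linked counts without the 10 genes that hold the most from 0.600% ± 0.374 to 1.71% ± 0.619. From the 40 to 50% bin to the 70 to 80% bin the share of those markers rose by a log2 ratio of 1.55 ± 1.08 in 4 arms while that of X-linked counts, 72.6% of them on those 10 genes, changed by -0.05 ± 0.28. Without the 10 genes the X-linked share went from 1.54% ± 0.566 (6 arms) to 3.28% ± 1.35 (4 arms) between these bins. X-linked counts outside the 10 genes thus rose along with the markers, and RNA from other cells cannot be told apart from a change in germ cells for either part. Transcription of the X in oocyte-forming germ cells stays a hypothesis: in gld-2 gld-1 arms, which lack such cells, the median difference from the N2 change was -5.09, a value it predicts. That difference rests in large part on gld-2 gld-1 posterior arm 2, without which it was -1.98 with 0 genes called. The distal region of this arm had 2.80% of its counts on markers of other cell types, against 0.0395% to 0.0676% in the other 3, so RNA of such cells in it may add to the difference.

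The mir-35 family was higher in proximal regions of N2 arms, with a median log2 of 5.68 over its 13 called members. Thinning every region to 11827 counts left a median of 4.50 over these 13, and scaling to the miRNAs outside the family left 4.11. These bounds were set on members chosen because they were called, which was wrong: over all 15 tested members the medians were 1.46 ± 2.54 and 0.89 ± 2.60 (2.70 before). Of the 15, 12 were higher in proximal regions under either setting. For single members, lower depth of distal regions and a few miRNAs taking most of the counts therefore cannot be told apart from a change of the family. For the family as a sum, the ratio of its counts to all other miRNA counts rose by log2 3.83 ± 2.202 as counted (5 of 5 arms). In thinned regions it rose by 3.82 ± 2.201 (5 of 5 arms, lowest 0.06). Thinning at random leaves this ratio unchanged on average by construction, so no conclusion on depth follows. Without the 10 most abundant other miRNAs, which held 43.3% ± 4.84 of other counts in distal and 53.7% ± 4.00 in proximal regions, the ratio rose by 4.12 ± 2.13 (5 of 5 arms, lowest 0.448). Leaving out miRNAs whose share is higher in proximal regions raises that change by construction, so no conclusion on such miRNAs follows. No biological explanation was tested, since the small RNA series holds N2 alone.

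For sygl-1, a target of GLP-1 signalling, the proximal level in N2 was above the distal one (log2 1.33). Leaving out dropout sections and adding the labelled shift gave 1.71, so the counts in these sections are not the whole cause. That setting kept 1 N2 section, of 1 arm, between 0 and 10% of the arm. It cannot bring back lost distal RNA, so such loss cannot be told apart from a proximal rise. The isoform that leads in distal regions held 99.98% of the proximal counts, which argues against another transcript end as the cause. Expression in oocyte-forming germ cells is a hypothesis: the gld-2 gld-1 minus N2 difference was -3.85, a value it predicts. Also open is the call itself, which ended without any one of the 6 N2 arms (edgeR adjusted p = 0.0514 to 0.261). The same holds for the difference, which did not pass without gld-2 gld-1 posterior arm 2 (edgeR adjusted p = 0.166).

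A difference between groups set apart 218 genes whose change along the arm differed between gld-2 gld-1 and N2, or 1 to 352 when single arms were left out, and sygl-1 was among them. Samples far from the others were looked for in 42 groups of values, of which chance would pick out about 1 in 20. Among gld-2 gld-1 arms, posterior 1 had 39570338 counts, with 29962344 in the next. Posterior 2, which unlike the other arms of this mutant had 0 dropout sections, had sygl-1 at 36.8 CPM, with 6.46 in the next. It had fln-1 at 892 CPM, with 544 in the next. Among N2 proximal regions, that of posterior 1 had cdr-4 at 142 CPM (next 43.8) and that of anterior 3 had tth-1 at 212 CPM (next 57.03). In the uncut poly(A) libraries, the spike-in transcripts that no comparison used made up 35.6% and 37.3% of counts in libraries 2 and 3.

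Samples were also regrouped in other ways. Between end regions of N2 arms 1 of 32 splits gave as many genes as the real 1547, with 386 in the highest other, and for the 218 genes 1 of 21 did, with 1 in the highest other. For gld-2 gld-1 against N2 it was 1 of 100 (2712, highest other 820), and between the mutants 1 of 35 (2991, highest other 1186). No other split drawn reached any of these 4 counts, which argues against chance without excluding it. Each share is the lowest its splits could give. For the 218 genes 21 of 210 possible splits were used, and their count fell to 1 without gld-2 gld-1 posterior arm 2. For 3' ends another split gave as many (1 gene, 2 of 32, highest other 1). For the middle regions of N2 (16 genes, 6 of 100 splits, highest other 1734) and their miRNAs (30, 10 of 100, highest other 72) splits exchanged regions within arms, and the highest had the distal region in the place of the middle one in 5 of 6 arms for genes and the proximal one in 5 of 5 for miRNAs. Such splits carry the difference between the ends, so nothing about chance follows from them. Where the real count was 0 every split gives as many, so nothing follows for glp-1(ar202) against N2 (0 by edgeR, 1115 genes at an unadjusted p under 0.05, 79 by DESeq2; 100 of 100, highest other 2) or for the difference of its change along the arm from that of N2 (0 by edgeR, 319 genes at an unadjusted p under 0.05, 6 by DESeq2; 21 of 21, highest other 61). Splits were too few for a share under 0.05 along gld-2 gld-1 arms (real 0 by edgeR, 785 and 24; 8 of 8, highest other 0), along glp-1(ar202) arms (5; 3 of 8, highest other 67), between sides (0 by edgeR, 88 and 2; 10 of 10, highest other 0) and for miRNAs between end regions (91; 1 of 16, highest other 0).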

How the results depend on the processing

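Of 17 results that answer a comparison, the counts for gld-2 gld-1 against N2 whole arms (2712; 1936 to 3559 over all settings but the arms left out in turn, 1919 to 3021 over those) and for miRNAs between end regions (91; 69 to 120, and 83 to 124) stayed within 1.5 times under every alternative. For gld-2 gld-1 against glp-1(ar202) only the fit without 1 arm moved it further (1947 to 4218). For the others the values below apply, and where no cause is given the cause was not tested. Left-out arms leave fewer samples, and no filter tests more genes, by construction. Leaving out dropout sections, alone or with the labelled shift, was chosen after the data were seen.

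For N2 end regions (1547 genes) the count was 227 with no replicate block, 2963 with sections weighted equally, 3735 with the labelled shift added and 898 with it subtracted, 801 without the earlier barcode set, 2477 without dropout sections, 4077 without them and with the shift, and 467 to 1826 without single arms. For N2 middle regions (16) it was 8 with DESeq2 size factors, 29 by the Wald test, 73 with no filter, 46 with 4 parts per arm, 0 with no replicate block, 0 weighted equally, 307 and 0 with the shift added and subtracted, 0 without dropout sections, 477 without them and with the shift, and 0 to 27 without single arms. Along gld-2 gld-1 arms (0 by edgeR, 785 at an unadjusted p under 0.05) it was 24 by the Wald test, 177 with no filter, 1 with the shift, 1 without dropout sections, 7 with both, and 0 to 0 without single arms. Along glp-1(ar202) arms (5) it was 0 with size factors, 989 by the Wald test, 514 with no filter, 0 with 4 parts per arm, with no replicate block, weighted equally, without sections under 10000 counts and with the shift subtracted, 638 with it added, 104 without dropout sections, 874 with both, and 0 to 498 without single arms. For the gld-2 gld-1 minus N2 difference (218) it was 398 with size factors, 1164 by the Wald test, 976 with no filter, 812 with 4 parts per arm, 1060 with no replicate block, 570 weighted equally, 390 without sections under 10000 counts, 1941 and 137 with the shift added and subtracted, 59 without the earlier barcode set, 371 without dropout sections, 2046 with both, and 1 to 352 without single arms. For the glp-1(ar202) minus N2 difference (0 by edgeR, 319 at an unadjusted p under 0.05) it was 6 by the Wald test and 0 otherwise.

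For glp-1(ar202) against N2 whole arms (0 by edgeR, 1115 at an unadjusted p under 0.05) the count was 79 by the Wald test, 686 with no filter and 0 to 1 without single arms. Between N2 sides it was 2 by the Wald test and 16 with no filter for mRNA (0 by edgeR, 88 at an unadjusted p under 0.05). For miRNAs between sides (7) it was 0 with size factors, 12 by the Wald test, 11 with no filter, 0 weighted equally and 0 to 7 without single arms. For miRNAs of middle regions (30) it was 0 with size factors, 14 with no filter, 0 weighted equally and 0 to 34 without single arms. For poly(A) against total RNA (0 by edgeR, 2127 at an unadjusted p under 0.05) it was 1260 by the Wald test and 0 to 8677 without single libraries. For 3' ends (1) it was 2 without dropout sections and 0 to 1 without single arms. The uncut mir-35 share (53.1%) was 60.9% with TMM scaling and 50.9% to 55.7% without single libraries. Of 270 list tests camera called 73, and 2 with an estimated correlation and 33 by fry.

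Across genes, residuals of mRNA arms with the same number had a median correlation of -0.011 over 31 pairs, which include pairs of different genotypes. Within N2, anterior and posterior arms of the same number had 0.271, -0.103 and -0.05, and those of different numbers -0.168 to 0.248. Within gld-2 gld-1 the pairs of the same number had 0.154, and within glp-1(ar202) 0.127. With 2 arms per side, pairs of these mutants mirror each other. Whether the numbers pair mRNA arms thus stays open. The 2 pairs of miRNA arms with the same number had 0.146 and 0.441, against a median of -0.243 over 4 other pairs, and were too few to decide. With the number as a replicate block the counts were 1936 (gld-2 gld-1 against N2), 0 (glp-1(ar202) against N2, 1634 at an unadjusted p under 0.05), 2748 (between the mutants), 1 (sides, mRNA), 11 (sides, miRNA) and 0 (poly(A), 627 at an unadjusted p under 0.05).

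For single genes and miRNAs named, 185 results had 3033 values under alternatives: 2545 kept their side of the threshold (34 of them, not called, changed sign), 435 lost a call, 50 gained one and 3 turned direction. Of the 185, 98 never lost a call or turned. The 3 were glh-1 in N2 end regions, from -1.87 to 0.18 with sections weighted equally (limma adjusted p = 0.871), and him-3, from 0.02 to -0.78 with the shift added (edgeR adjusted p = 0.0239) and -0.91 also without dropout sections (edgeR adjusted p = 0.012). Over its alternatives the adjusted p of him-3 ran from 0.012 to 0.995. For lists, 397 values kept their side (55 changed sign), 127 lost a call (3 changed sign) and 16 gained one. Low counts of the distal regions, down to 24841, limit what can be said about distal mRNAs.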

Other observations

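Without dropout sections and with the positions of the labels, levels of single germline mRNAs were followed along the arm. In N2 the yolk receptor gene rme-2 stood at 61.1 ± 49.3 CPM between 10 and 20% of the arm (6 arms) and 670 ± 137 between 70 and 80% (4 arms). For puf-5 the levels were 53.8 ± 39.01 and, between 80 and 90% (4 arms), 951 ± 567 CPM, and for lin-41 they were 15.7 ± 13.0 and 203 ± 92.6. The meiotic axis gene him-3 stood at 131 ± 37.9 CPM between 10 and 20%, 234 ± 53.5 between 70 and 80% and 98.3 ± 63.8 from 90% on (3 arms). In glp-1(ar202) arms sygl-1 was at 68.7 ± 56.8 CPM between 10 and 20% and 309 ± 31.4 between 50 and 60% (4 arms each). These bins were described and not tested.

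The test of N2 end regions was repeated in that setting, which was chosen after the data were seen and leaves 5 proximal regions against 6 distal ones. Of the oocyte maturation and eggshell genes, 19 of 23 rose and 3 fell, with rme-2 at log2 0.83, oma-2 at 1.03 and puf-5 at 1.33 (camera adjusted p = 0.00203, adjusted p = 0.414 with an estimated correlation). Of the maternal polarity and embryonic fate genes 16 of 26 rose and 0 fell, with pos-1 at 1.13 and mex-5 at 0.69 (camera adjusted p = 0.00287, adjusted p = 0.23 with an estimated correlation). In meiotic prophase 0 of 36 rose and 14 fell, with htp-1 at -1.69, syp-1 at -1.07 and him-3 at -0.91 (camera adjusted p = 0.00166, adjusted p = 0.414 with an estimated correlation). Of the P granule list 0 of 30 rose and 13 fell, with pgl-1, which encodes a P granule scaffold protein, at -1.01 (camera adjusted p = 0.00349, adjusted p = 0.414 with an estimated correlation). All 12 mitochondrially encoded genes fell (median -1.44, camera adjusted p = 0.000195, adjusted p = 0.414 with an estimated correlation). The PUF gene fbf-2 fell by 2.17 and passed.

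Several genes present in glp-1(ar202) arms had no count in the 4 gld-2 gld-1 arms. The chitinase gene cht-1 was at least 6214-fold lower there, the lectin gene clec-266 at least 3656-fold and the planar polarity gene vang-1 at least 1966-fold, against a floor of 3 counts over the group. The cyclin D gene cyd-1 had 1 count in gld-2 gld-1 arms, with a glp-1(ar202) to gld-2 gld-1 ratio of 2241 (95% counting interval 401.6 to 88550).

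In small RNA of N2 regions the mir-58 (bantam) family made up 8.41% ± 3.06 of miRNA counts in distal, 15.5% ± 6.32 in middle and 16.6% ± 8.76 in proximal regions (n = 5), and the mir-63 to mir-66 cluster 4.17% ± 1.31, 9.52% ± 0.686 and 9.99% ± 1.04. The uncut CEL-Seq libraries stood in no comparison. Across genes, which are not independent replicates, their rank correlations with the summed sections of the same side were 0.931 (anterior, 8654 genes) and 0.929 (posterior, 8595 genes). For 277 miRNAs that of uncut and sectioned anterior arms was 0.860. In the uncut libraries, msp transcripts made up 4.47e-06% of counts in poly(A) library 1, 0.0178% and 0.0209% in libraries 2 and 3, and 0.00159% and 0.00144% in total RNA. Of counts with ERCC transcripts included, ribosomal RNA made up 56.3% and 60.2% in total RNA, 0.684% in poly(A) library 1 and 14.7% and 11.8% in libraries 2 and 3.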
